A study of Mus musculus with 6 samples.

How the data were processed

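The values used were gene counts deposited by the authors, 1 column per library, as raw whole numbers over 48795 Ensembl gene identifiers and not divided by depth or gene length. Per the submitters' processing notes, reads were trimmed with cutadapt 1.18, aligned with HISAT2 to GRCm38 (mm10) and counted per gene with HTSeq 0.11.1. The HISAT2 version, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes can be shared between them. Total counts were 19309576 to 19700249 per library, and 20012 identifiers had no count in any library. Identifiers were matched to symbols, coordinates and exons with GENCODE M21, which left 446 identifiers with 0.0759% of the counts unmatched.

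Genes were filtered with filterByExpr at its defaults (minimum count 10, minimum total 15), which left 16861, and scaled with TMM. Double knockout was compared with wild type by edgeR's quasi-likelihood test with group as the only term and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. Levels are counts per 1000000 (CPM) scaled with TMM and folds are log2 of double knockout over wild type. The SE of a fold is its size divided by the square root of the F statistic. For genes with 1 to 3 counts over the WT libraries the ratio of counts per library size is given with an exact binomial 95% interval. A sex covariate was not run, since counts of Y-linked genes and Xist were alike in all 6 libraries. In simulated data of this size with 200 changed genes the test recovered 68% of genes changed 1.5-fold and 85% of those changed 2-fold, and 6.71% of its calls were unchanged genes.

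The test, its threshold, the gene lists, the rule for named genes and all alternatives except 1 were chosen before the data were examined. Named genes were Kdm1a and Kdm5c, then the 12 largest rises and the 12 largest falls past the threshold with a mean of at least 1 CPM in the higher group and no overlap between groups, then the 5 rises and 5 falls with the smallest adjusted p. In each list up to 4 members past the threshold with the smallest adjusted p were named, or the 2 with the smallest p where none passed. This rule counted predicted genes, clones and pseudogenes but passed them over for names, and a gene named outside it is said to be named after its value was seen.

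The 32 lists were germline genes, developmental transcription factors bound by Polycomb, CoREST partners with H3K4 methyltransferases, other histone lysine demethylases, Polycomb subunits, presynaptic release, glutamate receptors and postsynapse, voltage-gated channels, clustered protocadherins, neuropeptides and receptors, pyramidal and granule cell identity, immature neurons, immediate early genes, interneurons, astrocytes, reactive astrocytes, homeostatic microglia, activated microglia, oligodendrocytes, their precursors, vascular cells, choroid plexus with ependyma, neighbouring regions, erythrocytes, interferon response with antigen presentation, mitochondrial mRNAs, nuclear oxidative phosphorylation, ribosomal proteins, cholesterol synthesis, glucocorticoid response, p53 targets, and unfolded protein with integrated stress responses. Each was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists.

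Alternatives were RLE scaling, library size alone, DESeq2, limma-voom, no filter on low counts, at least 1 CPM in 3 libraries, a replicate block, leaving out each library, thresholds of 0.01 and 0.1, a test against a 1.2-fold change, and for lists an estimated correlation and fry. With an estimated correlation camera takes its degrees of freedom from the libraries and not from the genes, so it has little power with 6 libraries. A loess correction of each library for GC content (span 0.3) was added after the data were seen. Results that rest on items withheld for evaluation are not reported here. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.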

Results

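Polyadenylated RNA was sequenced from the hippocampus of mice that lost 2 histone demethylases in adulthood and from wild-type (WT) mice. KDM1A (LSD1) removes mono- and dimethylation from lysine 4 of histone H3, and KDM5C removes di- and trimethylation from the same residue. The double knockout (KO) carried floxed alleles of both genes and CreERT2, a recombinase that acts only after tamoxifen and that was driven by the CamKIIα promoter in principal neurons of the forebrain. Mice of both groups received tamoxifen, the labels placing the age at 2 to 3 months, and the comparison asks how hippocampal transcript levels differ once both enzymes are removed from these neurons. There were 3 libraries per group. No group lacked only 1 of the enzymes, so the share of each cannot be told apart. Nor can an effect of the recombinase itself, if WT mice did not carry it. Total gene counts were 19700249, 19309576 and 19440291 in the WT libraries and 19411611, 19342337 and 19637352 in the KO libraries. All 6 libraries held 3100 to 3404 counts from 4 Y-linked genes and 1 to 13 from Xist, so sex did not vary with genotype. The first principal component of log2 counts per 1000000 (CPM) held 54.5% of the variance and placed the WT libraries between -28.4 and -22.9 and the KO libraries between 23.9 and 26.4.

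Kdm1a transcript level in the KO fell by 47.7% (95% interval -52.1 to -42.8%), and every KO library lay below every WT library. Kdm1a (ENSMUSG00000036940, chromosome 4, 136550540 to 136602723, minus strand, GRCm38) measured 73.7 ± 3.95 CPM in WT and 38.6 ± 1.29 CPM in KO (mean ± SD, n = 3 each). Its log2 fold change was -0.93 (SE 0.0651) with an adjusted p of 4.32e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Kdm5c (ENSMUSG00000025332, chromosome X, 152233020 to 152274535, plus strand) measured 79.5 ± 2.97 CPM in WT and 70.6 ± 4.67 CPM in KO. Its log2 fold change of -0.17 (SE 0.0640) did not pass the threshold over all genes (adjusted p = 0.143, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Adjusted over the list alone, that is over these 2 genes, the edgeR quasi-likelihood p with Benjamini-Hochberg adjustment was 0.0186. All 3 KO values of Kdm5c, 65.3 to 74.3 CPM, lay below the WT values of 77.2 to 82.8 CPM, and the 95% interval of the difference ran from -18.6 to -3.12%.

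These are whole-gene counts, which check the labels only in part. The deleted exons 5 and 6 of Kdm1a span 200 of the 3008 bases (6.65%) of the main annotated transcript, at chromosome 4, 136572218 to 136573165. Exons 11 and 12 of Kdm5c span 345 of 6449 bases (5.35%), at chromosome X, 152253424 to 152253861. The Kdm5c span is a whole number of codons and the Kdm1a span is not. All of this holds if exons are numbered as in GENCODE. Whether this difference bears on the smaller fall of Kdm5c was not tested. The size of that fall does not decide whether its exons were deleted. Glia, interneurons and other cells without the recombinase keep both genes intact, and their transcripts are part of the same libraries.

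**Figure D1:**
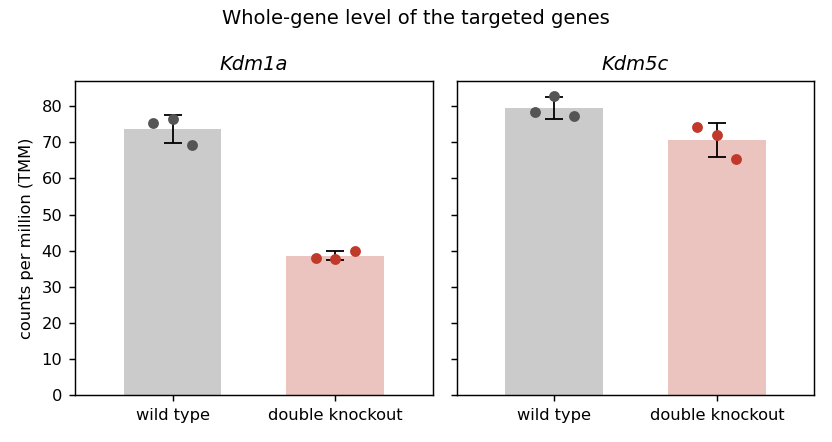
Whole-gene level of Kdm1a and Kdm5c in CPM, with 1 point per library, bars at the group mean and error bars of 1 SD (n = 3 per group). Kdm1a averaged 73.7 in wild type and 38.6 in double knockout, and Kdm5c 79.5 and 70.6.

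The KO hippocampus gained transcripts far more than it lost them. Of 16861 genes tested, 995 rose and 177 fell, and of those that changed at least 2-fold 352 rose and 4 fell. The largest rises were in genes with hardly a read in WT. C1ql4, which encodes a secreted C1q-related protein, had 1 read over the 3 WT libraries and 369 over the 3 KO libraries, a ratio of counts per library size of 364 (95% counting interval 65 to 14425). Tcf24, a basic helix-loop-helix transcription factor, rose from 0.328 ± 0.170 to 46.8 ± 2.19 CPM (mean ± SD, n = 3 each). Across the 995 genes the median log2 fold change was 0.74, against -0.33 for the 177 that fell, and the median over all tested genes was -0.01. Adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment is the threshold for every gene said to have risen or fallen here and in what follows.

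Among the 12 largest rises, 10 came from a WT mean below 0.2 CPM. Tmem30b, a subunit of phospholipid flippases, went from 1 read to 217 (ratio 214, 95% counting interval 38.0 to 8499). Otop1, a proton channel of the inner ear and of taste cells, went from 3 reads to 284 (ratio 93.4, interval 31.7 to 456), and Aqp5, a water channel of salivary and lacrimal glands, from 3 to 198 (ratio 65.1, interval 22.0 to 319). The phosphatase gene Ppm1n went from 2 reads to 194 (ratio 95.7, interval 26.2 to 796). Fgf3, a growth factor of inner ear development, went from 1 to 82 (ratio 80.9, interval 14.1 to 3235), and the helix-loop-helix factor Bhlhe23 from 3 to 228 (ratio 75.0, interval 25.3 to 366). Nup62cl, a relative of a nuclear pore protein, rose from 0.189 ± 0.128 to 17.0 ± 1.02 CPM, and Tcfl5, a transcription factor of spermatocytes, from 0.119 ± 0.164 to 10.9 ± 0.673 CPM. Ltbp2, a protein of the extracellular matrix, rose from 0.326 ± 0.177 to 18.8 ± 2.65 CPM. In all, 28 genes went from a WT mean under 0.2 CPM to a KO mean of at least 1 CPM.

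The 5 smallest p-values among genes that rose belonged to Tcf24 (ENSMUSG00000099032, chromosome 1, 9960163 to 9967932), Prph, Spint1, Nup62cl and Atp2a3. Prph (ENSMUSG00000023484, chromosome 15, 99055174 to 99058978) encodes peripherin, an intermediate filament of peripheral neurons, and rose from 1.89 ± 0.471 to 57.5 ± 2.91 CPM (log2 fold change 4.92, SE 0.126). Spint1 (ENSMUSG00000027315, chromosome 2, 119237362 to 119249527), an inhibitor of serine proteases in epithelia, rose from 1.98 ± 0.132 to 30.8 ± 1.67 CPM (3.95, SE 0.115). Atp2a3 (ENSMUSG00000020788, chromosome 11, 72961169 to 72993044), a calcium pump of the endoplasmic reticulum, rose from 11.3 ± 0.461 to 75.4 ± 7.29 CPM (2.73, SE 0.0872). Their adjusted p-values in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 2.28e-11, 8.25e-11 and 2.23e-10, and that of Tcf24 was 1.40e-11.

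Falls were small. Slc24a2, a sodium-calcium exchanger of neurons, had the smallest p after Kdm1a and fell from 612 ± 42.0 to 426 ± 21.7 CPM (log2 fold change -0.52, SE 0.0625). Npy2r, a receptor for neuropeptide Y, fell from 65.8 ± 2.1 to 47.2 ± 2.55 CPM, Nectin3, an adhesion protein, from 38.3 ± 2.69 to 26.2 ± 0.831 CPM, and Nwd2 from 45.3 ± 0.898 to 34.0 ± 1.55 CPM. The 12 largest falls included Kdm1a, the long noncoding antisense transcript Panct2 (-1.07, SE 0.197), the iodotyrosine deiodinase gene Iyd (4.10 ± 0.312 to 2.04 ± 0.565 CPM) and the neuropeptide gene Cort (-0.74, SE 0.143). The other 8 were Pparg (-0.98), Apold1 (-0.94), Etnppl (-0.91), Morc2b (-0.89), Cbx8 (-0.69), Frmd7 (-0.67), Zfp995 (-0.63) and Mcm5 (-0.61). Each of these 8 lost its call on leaving out at least 1 library. The largest adjusted p-values so reached (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) were 0.195, 0.0624, 0.0790 and 0.207 without KO replicate 3 for Apold1, Etnppl, Cbx8 and Mcm5, 0.147 without KO replicate 2 for Pparg, and 0.0758, 0.172 and 0.137 without KO replicate 1 for Morc2b, Frmd7 and Zfp995. Smaller adjusted p-values in the same test that also missed the threshold were 0.0827, 0.113, 0.0679 and 0.129 for Pparg, Mcm5, Frmd7 and Zfp995 without WT replicate 1. They were 0.138, 0.0914, 0.0576, 0.157, 0.0709 and 0.0884 for Pparg, Apold1, Morc2b, Frmd7, Zfp995 and Mcm5 without WT replicate 2. They were 0.12, 0.0626 and 0.0581 for Apold1, Frmd7 and Mcm5 without WT replicate 3, 0.0542 and 0.0585 for Pparg and Cbx8 without KO replicate 1. They were 0.103, 0.0699, 0.123, 0.0976 and 0.0879 for Apold1, Morc2b, Frmd7, Zfp995 and Mcm5 without KO replicate 2, and 0.0996 and 0.0786 for Pparg and Frmd7 without KO replicate 3. With all 6 libraries kept, DESeq2 ended the calls of Frmd7 (adjusted p = 0.137), Pparg (0.0976), Mcm5 (0.0827), Morc2b (0.0625), Etnppl (0.0580) and Zfp995 (0.0546). A replicate block ended those of Apold1 (0.0665), Frmd7 (0.0637), Zfp995 (0.0587) and Pparg (0.0566), and limma-voom those of Frmd7 (0.0553) and Apold1 (0.0533). GC correction ended those of Zfp995 (0.0537) and Frmd7 (0.0519). Scaling by library size alone ended that of Frmd7 (0.0534). Among the 12 largest rises 0 lost their call in any alternative that was run gene by gene. Besides Panct2 and Iyd, the genes that fell at least 2-fold were Rgs13 (-1.54) and the pseudogene Gm37313 (-1.23), both named after their values were seen. The number that fell at least 2-fold was 2 without WT replicate 2 or KO replicate 3, 7 without WT replicate 3 and 8 without KO replicate 1.

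**Figure D2:**
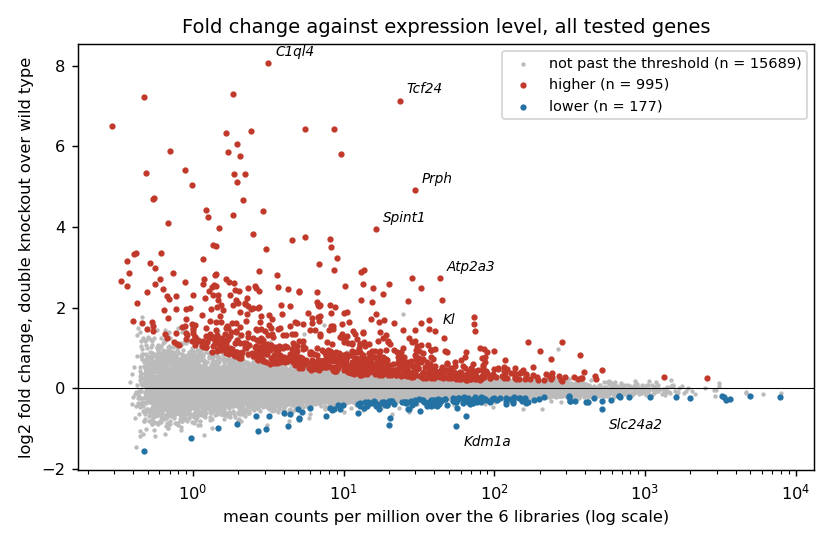
Log2 fold change of double knockout over wild type (y axis) against mean CPM over the 6 libraries (x axis, log scale) for each tested gene, with the 995 genes that rose in red, the 177 that fell in blue and the rest in grey. Rises of more than 2 log2 units have no counterpart among the falls.

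**Figure D3:**
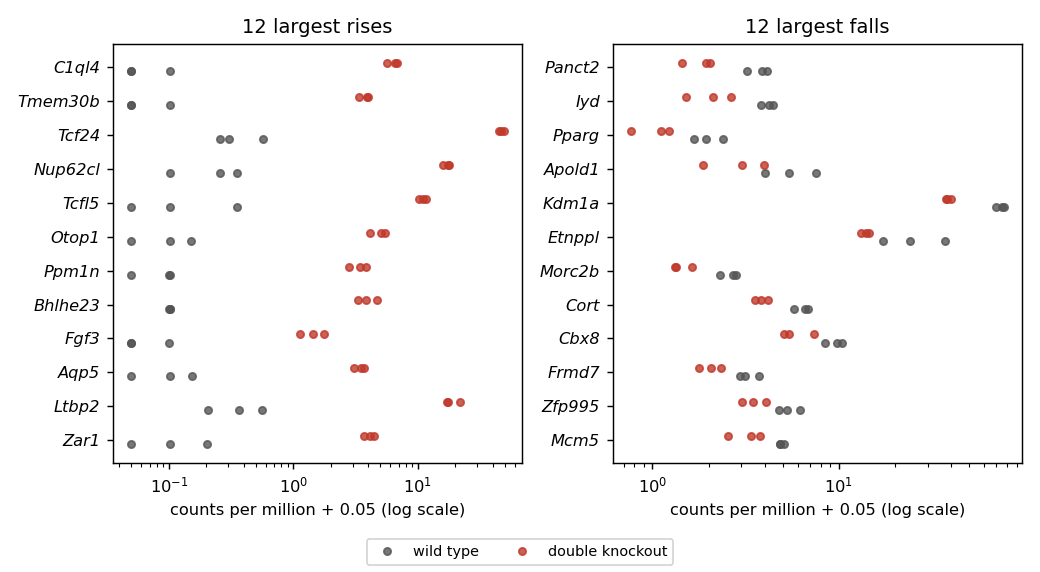
CPM plus 0.05 (x axis, log scale) in each library for the 12 largest rises and the 12 largest falls, with wild type in grey and double knockout in red. For each of these genes every library of one genotype lies on the same side of every library of the other, as the rule for choosing them required.

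Of the genes that rose, 990 were higher in every KO library than in any WT library, and 176 of those that fell were lower in every KO library. Such separation held for 25.2% of all tested genes, and chance gives 10% for 3 against 3. Passing the threshold itself favours separation, so the 990 and 176 are no added evidence. Leaving out 1 library moved the count of falls to 323 without WT replicate 3, 102 without KO replicate 1, 67 without KO replicate 2 and 48 without KO replicate 3, and the total of changed genes to 724 without KO replicate 3. The labels do not say that libraries of a group came from separate animals, so p-values measure only the spread between these samples, and intervals on ratios of counts cover counting error only.

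A minority of the germline genes that could be tested rose, and Zar1 was 1 of the 12 largest rises. The list of genes normally limited to germ cells had 54 members, of which 17 were expressed enough to test, and 4 rose and 0 fell (5 and 0 adjusted over the list alone). Zar1, an oocyte factor, rose from 4 reads to 238 over the 3 libraries (log2 fold change 5.75, SE 0.398), and Boll, a regulator of meiotic translation, from 2 reads to 101 (ratio 49.8, 95% counting interval 13.4 to 417). Tdrd6, a Tudor protein of spermatids, rose from 1.09 ± 0.164 to 4.41 ± 0.573 CPM, and Meioc, required in meiotic prophase, from 0.536 ± 0.135 to 2.1 ± 0.349 CPM. The list was higher as a set in camera with a preset correlation (adjusted p = 0.0325), though its median log2 fold change was 0.06 and its mean 0.94. The adjusted p was 0.403 with an estimated correlation, 0.315 with no filter on low counts, and 0.0693, 0.182, 0.0634 and 0.0906 without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 3. A gene nearly silent in WT passed the filter only if it was high in KO. The 17 tested genes thus favour rises, and their set test cannot speak for the 54.

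Of 114 listed developmental transcription factors that Polycomb silences in most adult tissues, 20 had enough counts to be tested, and 2 rose and 0 fell (3 and 0 adjusted over the list alone): Sox18, a factor of vascular development (log2 fold change 0.71, SE 0.137), and Tbx1, a factor of pharyngeal development (0.89, SE 0.243). The call of Tbx1 was lost in DESeq2 (adjusted p = 0.120), in limma-voom (0.0539), and in edgeR with a replicate block (0.0532) or after GC correction (0.0718), and also without WT replicates 1, 2 and 3 and KO replicates 2 and 3 (edgeR quasi-likelihood adjusted p with Benjamini-Hochberg adjustment of 0.135, 0.0576, 0.0842, 0.0724 and 0.219). The 20 had a median log2 fold change of 0.36 and were higher as a set (camera adjusted p = 0.0104, adjusted p = 0.336 with an estimated correlation and 0.0708 with no filter on low counts). As in the germline list, a factor nearly silent in WT could be tested only if it was high in KO, which favours rises.

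Among chromatin regulators few genes changed, as among all tested genes, of which 6.95% changed. Of 28 tested members of the CoREST complex and the H3K4 methyltransferases 3 rose and 0 fell (4 and 0 adjusted over the list alone). They were Rest, the repressor of neuronal genes that recruits CoREST (6.24 ± 0.706 to 13.9 ± 0.230 CPM, log2 fold change 1.15, SE 0.113), Rcor2, a CoREST scaffold (0.65, SE 0.0929), and Hdac1, its deacetylase (0.55, SE 0.0942). Of 30 Polycomb subunits 1 rose, Epop (0.96, SE 0.0709), and 1 fell, Cbx8 (-0.69, SE 0.152), with the same counts adjusted over the list alone. Of 22 other histone lysine demethylases Kdm4b rose (0.26, SE 0.0587) and Phf8 fell (-0.28, SE 0.0678), again 1 and 1 adjusted over the list alone. Cbx8, Kdm4b and Phf8 lost their calls without KO replicate 3 (edgeR quasi-likelihood adjusted p with Benjamini-Hochberg adjustment of 0.0790, 0.0889 and 0.123). So did Cbx8 without KO replicate 1 (0.0585), Kdm4b without WT replicate 1 (0.0545) or KO replicate 2 (0.0887) and Phf8 without WT replicate 2 (0.0521) or KO replicate 2 (0.0891). In camera the CoREST, Polycomb and demethylase lists did not pass (adjusted p = 0.926, 0.199 and 0.458), and the first had a median of -0.04 against a mean of 0.05.

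Genes of the presynaptic release machinery were lower as a set by camera (adjusted p = 0.00896, adjusted p = 0.316 with an estimated correlation), although the mean level of the set per library overlapped between the groups. Of 50 tested, 2 rose and 6 fell (2 and 8 adjusted over the list alone), with a median log2 fold change of -0.08. Doc2a and Doc2b, calcium sensors of vesicle fusion, rose (1.65, SE 0.153, and 0.34, SE 0.0667), while Unc13a, a vesicle priming factor (579 ± 37.5 to 466 ± 11.7 CPM), and Rims1, an active zone scaffold (200 ± 15.8 to 165 ± 3.16 CPM), fell. Rims1 lost its call without KO replicate 1, 2 or 3 (edgeR quasi-likelihood adjusted p with Benjamini-Hochberg adjustment of 0.0585, 0.0888 and 0.0855), and the number of falls was 3 without WT replicate 1 or KO replicate 1 and 1 without KO replicate 2 or KO replicate 3.

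Of 66 voltage-gated channel genes tested, 10 rose and 2 fell (11 and 3 adjusted over the list alone), and the set did not pass camera (adjusted p = 0.926). The potassium channel genes Kcns1 (10.5 ± 0.101 to 23.6 ± 1.41 CPM), Kcng1 (53.2 ± 1.84 to 75.0 ± 5.08 CPM), Kcnh3 (112 ± 3.42 to 145 ± 4.33 CPM) and Kcnc4 (84.3 ± 4.2 to 104 ± 2.95 CPM) rose, the last without passing after correction for GC content (edgeR quasi-likelihood adjusted p with Benjamini-Hochberg adjustment 0.0519). The falls, named after their values were seen, were in Kcnv1 (-0.35) and Kcnq5 (-0.20). The number of rises was 5 without KO replicate 1 and 6 without WT replicate 1, KO replicate 2 or KO replicate 3 or after GC correction, and the number of falls was 6 without WT replicate 3. Of 57 glutamate receptor and postsynaptic genes only Grin2d, an NMDA receptor subunit, rose (log2 fold change 0.54, SE 0.11) and 0 fell, as also adjusted over the list alone (camera adjusted p = 0.0511, 0.00802 without WT replicate 3 and 0.0323 without KO replicate 2). With all 6 libraries that set was lower in camera after GC correction (0.0141), with limma-voom (0.0197) and with no filter (0.0480). Of 52 clustered protocadherins 1 rose, Pcdhgc5 (0.48, SE 0.0633), and 0 fell, as also adjusted over the list alone (camera adjusted p = 0.329).

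Neuropeptides and their receptors, and markers of hippocampal principal neurons, also moved both ways. Of 52 peptide and receptor genes 9 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.0660, 0.0475 without KO replicate 2). With all 6 libraries the set passed with no filter (0.0485) and in fry (0.0260). The peptide gene Cartpt rose from 1.93 ± 0.0459 to 5.37 ± 0.696 CPM, and the receptor genes Adra2a (log2 fold change 0.77, SE 0.106) and Crhr1 (0.51, SE 0.0821) rose, while Npy2r and Cort fell. Of 47 pyramidal and granule cell markers 7 rose and 4 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.870), with a median of -0.04 and a mean of 0.05. Map3k15 rose from 2.45 ± 0.970 to 10.9 ± 1.52 CPM and Cacng5 from 10.6 ± 0.397 to 16.6 ± 0.504 CPM, while Nectin3 and the cation channel gene Trpc6 (31.8 ± 2.41 to 22.2 ± 1.93 CPM) fell, as did Iyd and Neurod6 (-0.34, named after its value was seen). The number of rises in that list was 4 without WT replicate 1, and the number of falls 10 without WT replicate 3. Of 25 genes of immature neurons 4 rose and 0 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.199). Sox4 (0.91, SE 0.159) and Igfbp2 (0.94, SE 0.177) kept their calls in all alternatives that were run gene by gene, and Sox11 (0.37) and Neurog2 (0.99) did not. Their edgeR quasi-likelihood adjusted p-values (Benjamini-Hochberg) were 0.144 and 0.229 without KO replicate 2, 0.138 and 0.0832 without KO replicate 1 and 0.137 and 0.134 without WT replicate 1. Sox11 also lost its call without WT replicate 3 (0.101) or KO replicate 3 (0.105), and Neurog2 without WT replicate 2 (0.145). With all 6 libraries kept, both lost it under RLE scaling (0.0505 for Sox11 and 0.0501 for Neurog2). Neurog2 also lost it in DESeq2 (0.0989), limma-voom (0.0721), with a replicate block (0.0634) and after GC correction (0.0540). Of 36 immediate early genes 1 rose, Nptx2 (0.53, SE 0.111), and 1 fell, Nr4a2 (-0.37, SE 0.0886), as also adjusted over the list alone. That set was lower in camera (adjusted p = 0.0202, adjusted p = 0.582 with an estimated correlation, and 0.296 without WT replicate 3, 0.0634 without KO replicate 1 and 0.11 without KO replicate 3). Nr4a2 itself had edgeR quasi-likelihood adjusted p-values (Benjamini-Hochberg) of 0.101, 0.0590 and 0.148 without WT replicate 1, WT replicate 2 and KO replicate 3, and Nptx2 of 0.05003 without WT replicate 1.

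Immune genes were higher in the KO. Of 44 tested genes of the interferon response and antigen presentation 8 rose and 0 fell (12 and 1 adjusted over the list alone), with a median log2 fold change of 0.23 (camera adjusted p = 0.000136, adjusted p = 0.316 with an estimated correlation). Bst2, a membrane protein that tethers budding viruses, rose from 2.84 ± 0.761 to 9.59 ± 0.770 CPM, H2-K1, a class I antigen-presenting molecule, from 20.6 ± 3.08 to 39.8 ± 3.83 CPM, and the interferon-induced GTPase gene Irgm1 from 9.05 ± 0.383 to 12.9 ± 0.993 CPM. H2-D1, also class I, rose from 25.6 ± 2.63 to 35.8 ± 4.38 CPM, although reads of H2 genes can be shared between near-identical copies. The number of rises in the list was 4 without KO replicate 1 and 3 without KO replicate 3, and H2-D1 had an edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.0557 without KO replicate 3.

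Markers of microglia and oligodendrocytes were higher as sets in camera with a preset correlation, with small medians and a few larger rises. Neither set passed fry (adjusted p = 0.0597 and 0.0884). Of 30 homeostatic microglial genes 29 had a positive log2 fold change with a median of 0.21, and 2 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 2.46e-06, adjusted p = 0.469 with an estimated correlation). Fcgr3, an immunoglobulin receptor, rose from 9.61 ± 0.324 to 25.2 ± 2.29 CPM, and Laptm5, a lysosomal protein, from 34.2 ± 2.51 to 41.8 ± 3.32 CPM, the latter with edgeR quasi-likelihood adjusted p-values (Benjamini-Hochberg) of 0.174, 0.0673, 0.222 and 0.153 without WT replicate 1, WT replicate 2, KO replicate 2 and KO replicate 3, 0.0687 after GC correction, and 0.0536 in limma-voom. All 32 oligodendrocyte markers had a positive log2 fold change with a median of 0.22, and 5 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 2.46e-06, adjusted p = 0.469 with an estimated correlation). Myelin basic protein, Mbp, rose from 2365 ± 160 to 2822 ± 146 CPM, Ppp1r14a from 7.82 ± 1.46 to 15.0 ± 1.93 CPM, Gsn from 50 ± 0.924 to 62.2 ± 5.08 CPM and Anln from 52.8 ± 4.72 to 64.9 ± 3.31 CPM. Apod rose as well (0.41; named after its value was seen). Without KO replicate 3, Mbp, Gsn and Anln lost their calls (edgeR quasi-likelihood adjusted p with Benjamini-Hochberg adjustment of 0.107, 0.0996 and 0.151), as did Mbp without KO replicate 2 (0.0564) and Anln without KO replicate 1 (0.0870). The number of oligodendrocyte genes that rose was 9 without WT replicate 1, 3 without KO replicate 1 and 1 without KO replicate 3, and 12 with no filter and 9 after GC correction.

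Activation genes of glia showed the same direction. In fry neither activated microglia nor reactive astrocytes passed as sets (adjusted p = 0.113 and 0.171). Of 23 genes of activated microglia 5 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00452, adjusted p = 0.538 with an estimated correlation). Cd63 (log2 fold change 0.65, SE 0.115), Ctsz (0.53, SE 0.104) and Csf1 (0.35, SE 0.0696) rose, and Lpl, which neurons also express, fell (-0.44, SE 0.0763). The other 2 that rose, named after their values were seen, were Apoe (0.29) and Axl (0.25), and the number of rises was 3 without WT replicate 1 or KO replicate 3. Of 24 reactive astrocyte genes 5 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.00304, adjusted p = 0.538 with an estimated correlation). Gfap, the intermediate filament of astrocytes, rose from 339 ± 21.7 to 450 ± 23.1 CPM, Serping1, an inhibitor of complement, from 6.65 ± 0.543 to 14.6 ± 3.38 CPM and Cd109 from 7.39 ± 1.46 to 13.3 ± 1.08 CPM. H2-D1, which the interferon list shares, and Sphk1 (1.5, named after its value was seen) were the other rises, and 3 remained in number without KO replicate 3. General astrocyte markers had a median of 0.07, and of 27 tested 1 rose, Btbd17 (0.53, SE 0.111), and 0 fell, as also adjusted over the list alone (camera adjusted p = 0.0521, 0.00392 without WT replicate 3). With all 6 libraries that set passed camera with limma-voom (0.0197), after GC correction (0.0292), with library size alone (0.0462) and with at least 1 CPM in 3 libraries (0.0486). Btbd17 had an edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.0558 without KO replicate 3.

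Other cell types gave a mixed picture. Of 34 interneuron markers 1 rose, the transcription factor Npas1 (16.8 ± 0.826 to 31.4 ± 1.21 CPM), and 0 fell, as also adjusted over the list alone, with a median log2 fold change of -0.02 and a mean of 0.01 (camera adjusted p = 0.812). Of 18 oligodendrocyte precursor markers 3 rose and 0 fell (4 and 0 adjusted over the list alone). They were C1ql1 (6.28 ± 0.969 to 16.8 ± 1.51 CPM), Matn4 (0.59, SE 0.0879) and Susd5 (0.68, SE 0.122), and the set passed camera with an adjusted p of 0.0180 (adjusted p = 0.469 with an estimated correlation, 0.1001 without WT replicate 1). Of 35 vascular markers Pdgfrb alone rose (0.37, SE 0.0971; 0 adjusted over the list alone), and its edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) was 0.0992, 0.0607, 0.0518, 0.111 and 0.201 without WT replicates 1, 2 and 3 and KO replicates 1 and 3 and 0.0623 after GC correction. That set had a camera adjusted p of 0.0138 (adjusted p = 0.582 with an estimated correlation, 0.0526 without KO replicate 1 and 0.173 without KO replicate 3). Of 24 choroid plexus and ependymal markers only Kl, the anti-ageing hormone klotho, rose (22.0 ± 1.37 to 58.9 ± 3.45 CPM) and 0 fell, as also adjusted over the list alone (camera adjusted p = 0.0127, adjusted p = 0.538 with an estimated correlation, 0.241 without WT replicate 2). Of 28 markers of neighbouring brain regions 8 rose and 1 fell, as also adjusted over the list alone (camera adjusted p = 0.0572, 0.0273 without WT replicate 1 and 0.0192 without KO replicate 2). With all 6 libraries that set passed with limma-voom (0.0317), with no filter (0.0338) and in fry (0.0356). Rspo1, an enhancer of Wnt signalling, rose from 0.760 ± 0.250 to 10.3 ± 1.63 CPM, Gpr151, a habenular receptor, from 0.622 ± 0.231 to 1.98 ± 0.319 CPM and Rgs9, a striatal regulator of G proteins, from 13.1 ± 0.408 to 18.4 ± 0.915 CPM, and Nwd2 fell. Of 7 erythrocyte genes 0 passed in edgeR, also adjusted over the list alone, or in DESeq2 and limma-voom (camera adjusted p = 0.0908). The near-identical globin genes Hba-a1 (0.47) and Hba-a2 (0.59) were the 2 with an unadjusted p under 0.05. Without WT replicate 3 both passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (0.00105 and 0.00154), as did their list in camera (adjusted p = 0.000844), which also passed with limma-voom and all 6 libraries (0.0304).

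Transcripts of the mitochondrial genome took a smaller share of the counts in KO, 3.82, 3.67 and 3.88% against 4.32, 4.25 and 4.21% in WT, and this share, a sign of RNA composition or quality, moved with genotype like the groups above. Of 10 tested mitochondrial mRNAs 0 rose and 6 fell, as also adjusted over the list alone (camera adjusted p = 0.000389, adjusted p = 0.403 with an estimated correlation). Mt-Nd2 fell from 4029 ± 126 to 3338 ± 226 CPM, mt-Cytb from 8401 ± 411 to 7256 ± 157 CPM, and mt-Nd4 (-0.28, SE 0.0608) and mt-Nd5 (-0.22, SE 0.0450) fell too. Correction of each library for GC content, an alternative added after the data were seen, left 0 of the 6 calls, with log2 fold changes of -0.15 for mt-Nd2 and -0.13 for mt-Cytb against -0.27 (SE 0.0523) and -0.21 (SE 0.0442) before it, while the set still passed camera after it (adjusted p = 0.0220). The number of falls was 2 without KO replicate 2 or KO replicate 3.

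Nuclear genes of oxidative phosphorylation had 0 of 74 past the threshold in edgeR, also adjusted over the list alone, and 0 in DESeq2 and limma-voom. Their median and mean were 0.01 while camera put them lower without passing (adjusted p = 0.861), and 1 had an unadjusted p under 0.05. Without WT replicate 2 the set was lower in camera (adjusted p = 7.94e-05), and Ndufs4 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (0.0207). Their smallest unadjusted edgeR quasi-likelihood p-values over all 6 libraries were 0.0294 for Ndufs4 (-0.17) and 0.0898 for Atp5g2 (0.26). Ribosomal protein genes were higher as a set, with a positive log2 fold change in 67 of 74 and a median of 0.12, but 0 passed the threshold in edgeR, also adjusted over the list alone, or in DESeq2 and limma-voom, and 4 had an unadjusted p under 0.05. Their camera adjusted p was 0.00896 (adjusted p = 0.741 with an estimated correlation, 0.993 without WT replicate 2 and 0.216 without KO replicate 2), and Rps3 (0.26) had an unadjusted edgeR quasi-likelihood p of 0.0204 and passed without WT replicate 3 (adjusted p = 0.0321 in the edgeR test with Benjamini-Hochberg adjustment) and with no filter (0.0451). Cholesterol synthesis genes were lower as a set with a median of -0.11 and 0 of 23 past the threshold in edgeR, also adjusted over the list alone, DESeq2 or limma-voom, and 7 at an unadjusted p under 0.05 (camera adjusted p = 0.0165, adjusted p = 0.670 with an estimated correlation, 0.262 without WT replicate 3 and 0.0906 without KO replicate 3). Hsd17b7 (-0.30) and Stard4 (-0.33) had the smallest unadjusted edgeR quasi-likelihood p-values there, 0.00905 and 0.0105, and passed without WT replicate 2 (adjusted p = 0.0298 and 0.0272 with Benjamini-Hochberg adjustment). Stard4 also passed with all 6 libraries and no filter (0.0466). Glucocorticoid-responsive genes had 0 of 21 past the threshold in edgeR, also adjusted over the list alone, DESeq2 or limma-voom, 7 at an unadjusted p under 0.05 and a median of -0.18. Tsc22d3 (-0.45) and Errfi1 (-0.20) had the smallest unadjusted edgeR quasi-likelihood p-values, 0.0164 and 0.0183. Tsc22d3 passed without WT replicate 1 (adjusted p = 0.00192 in edgeR with Benjamini-Hochberg adjustment) and, with all 6 libraries, with no filter on low counts (0.00553). That set was lower in camera (adjusted p = 0.0347, adjusted p = 0.688 with an estimated correlation), and the adjusted p was 0.241 without WT replicate 2, 0.433 without WT replicate 3, 0.0532 without KO replicate 1 and 0.0942 without KO replicate 3.

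Few genes of stress pathways changed, and neither set passed camera. Of 33 genes of the unfolded protein and integrated stress responses 2 rose and 1 fell, as also adjusted over the list alone (camera adjusted p = 0.626), with a median of -0.06 and a mean of 0.02. The chaperone gene Hspa1b, which shares sequence with Hspa1a, rose from 9.03 ± 1.43 to 18.9 ± 0.908 CPM and Psat1 from 111 ± 7.25 to 132 ± 5.71 CPM, while Hsph1 fell from 456 ± 36.3 to 362 ± 18.4 CPM. Psat1 had edgeR quasi-likelihood adjusted p-values (Benjamini-Hochberg) of 0.0859, 0.0760, 0.138 and 0.127 without WT replicate 1, WT replicate 2, KO replicate 2 and KO replicate 3. Of 23 p53 target genes Psrc1 (0.60, SE 0.0873) and Phlda3 (0.50, SE 0.0887) rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.469).

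**Figure D4:**
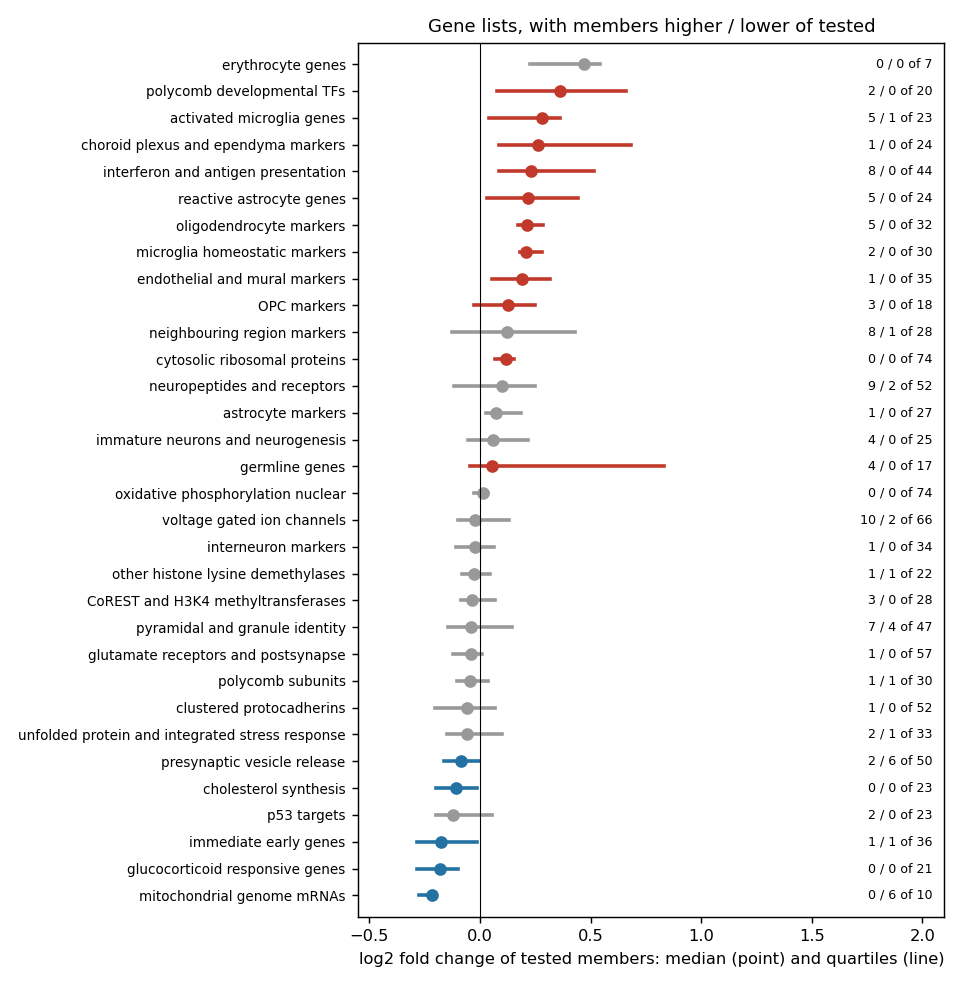
Median (point) and quartiles (line) of the log2 fold change, double knockout over wild type, of the tested members of each gene list, with members that rose / fell of those tested at the right. Red and blue mark lists higher and lower in camera with a preset correlation, and grey lists that did not pass. Erythrocyte genes have the largest median, 0.47 over 7 genes, without passing.

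Across the 32 lists, 16 passed camera with a preset correlation of 0.01, of which 11 were higher and 5 lower. With an estimated correlation camera put 0 past the threshold and 3 at an unadjusted p under 0.05, the smallest adjusted p being 0.316. Fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, put 8 lists past the threshold. Vascular, choroid plexus, immediate early, ribosomal, cholesterol and glucocorticoid sets did not pass fry (adjusted p = 0.302, 0.120, 0.468, 0.501, 0.438 and 0.526). For each of these sets, as for presynaptic release, the mean level per library overlapped between the groups.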

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

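The GC correction was chosen only after the results were seen. The other thresholds and the test against a 1.2-fold change were run for counts of genes only. In every other alternative Kdm1a was lower past the threshold, and Kdm5c was lower and past it in none. Of 100 named genes past the threshold, 71 passed in every such alternative that tested them, and of 16 lists 7 passed in every alternative of camera with a preset correlation. In data simulated at this depth and sample number the test recovered 68% of genes changed 1.5-fold.

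Against 1172 genes changed, 995 higher, 177 lower and 4 lower at least 2-fold, a threshold of 0.01 gave 661, 614, 47 and 2 by its construction, a threshold of 0.1 gave 395 lower, and a test against a 1.2-fold change gave 549, 536 and 13. With no filter, which admits more genes, 279 were lower and 10 of them at least 2-fold, and with at least 1 CPM in 3 libraries, which admits fewer, 2 were lower at least 2-fold. DESeq2 gave 2 lower at least 2-fold and GC correction gave 296 lower, and the cause was not tested. Leaving out 1 library gave 724 to 1424 changed, 48 to 323 lower and 2 to 8 lower at least 2-fold, with fewer samples in each fit. The 16 lists past the threshold became 0 with an estimated correlation. For the presynaptic, germline and Polycomb-bound developmental lists that estimate was -0.00413, -0.00239 and -0.0066. These lie under the preset 0.01, so greater correlation did not end their calls. What remains is that camera then has fewer degrees of freedom, set by the 6 libraries. A call lost this way is not evidence that a list was unchanged. In fry, which asks another question, 8 lists passed, while 10 of the 16 lost their call and 2 other lists gained one.

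Same-numbered samples did not deviate together (correlations 0.00465, -0.00921 and -0.0240), and no sample correlated best with its own number. With a replicate block 1109 genes changed, 960 higher and 149 lower, and 16 lists passed.

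The direction of some list tests reversed, and the cause was not tested. For voltage-gated channels the adjusted p was 0.959 with limma-voom, 0.992 with the block and 0.631 with GC correction, and for CoREST and methyltransferase genes 0.992 with the block and 0.925 with GC correction. With fry it was 0.438 for interneurons, 0.985 for oxidative phosphorylation, 0.898 for p53 targets and 0.631 for pyramidal and granule identity. Over all fits without 1 library, reversed or not, the camera adjusted p ran from 0.350 to 0.994 for CoREST, 7.94e-05 to 0.762 for oxidative phosphorylation, 0.586 to 0.993 for pyramidal and granule identity, 0.193 to 0.912 for stress responses and 0.363 to 0.930 for voltage-gated channels. For oxidative phosphorylation the reversed fits gave 0.762, 0.0830 and 0.366 without WT replicate 1, WT replicate 3 and KO replicate 1. The 7.94e-05, without WT replicate 2, kept the direction. No named gene reversed.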

Other observations

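The test of a lower share of excitatory neurons and the GC correction were chosen only after the results were seen, and so were the genes and families named here. Wnt ligands, secreted signals of development, had the smallest p for higher genes among 262 symbol families of at least 8 tested members: of 15 tested 9 rose and 0 fell (Fisher's exact test, adjusted p = 7.95e-06). Wnt2b rose from 4.31 ± 0.414 to 15.7 ± 1.79 CPM (mean ± SD, n = 3 each) and Wnt7b from 44.3 ± 2.90 to 64.7 ± 2.29 CPM. Wnt10b (log2 fold change 2.71) and Wnt1 (2.59) rose from under 0.5 CPM. Of 11 keratins 5 rose and 0 fell (Fisher's exact test, adjusted p = 0.0318), among them Krt9, a keratin of palm and sole skin, from 9.68 ± 1.48 to 43.7 ± 4.35 CPM. Fisher's test treats genes as independent, which members of a family need not be, so both p-values may be too small.

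The 28 genes nearly silent in WT included several transcription factors, of which 3 are given here, picked for their values and with no test of such factors as a group, and of the fixed list of developmental factors 2 of 20 tested rose. Myod1, a factor of skeletal muscle, rose from 0.173 ± 0.169 to 2.79 ± 0.440 CPM, Mesp1, of early mesoderm, from 0.121 ± 0.0797 to 2.40 ± 0.452 CPM, and Klf14 from 0.104 ± 0.00136 to 4.36 ± 0.955 CPM. Chrna3, a nicotinic receptor subunit abundant in the habenula, rose from 0.636 ± 0.256 to 3.41 ± 0.00945 CPM, while Slc17a6, also abundant there, did not pass (log2 fold change -0.49).

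Of the changed genes 84.9% were higher. The choice among scalings did not account for this, since 84.5% were higher with RLE scaling and 88.7% with library size alone. TMM factors ran only from 0.989 to 1.01, so these scalings were nearly alike and cannot exclude a scaling cause. Higher genes were richer in GC (median 54.4% against 47.2% in lower genes and 49.6% in all), and after GC correction 76.3% were higher, 70.2 to 90.5% on leaving out 1 library. The number higher went from 995 to 951 and the number lower from 177 to 296, which argues against GC content as the whole cause of the excess. Reads from a neighbouring higher gene are a candidate explanation for few, since 12.0% of higher genes lay within 5 kb of another, against 2.82 to 7.75% in 100 random sets. Derepression in the absence of both enzymes stays open and untested, and of the 10 splits of the 6 libraries 1, the real one, gave as many as 1172 genes and the highest other gave 1, though 10 splits are too few for a share under 0.05.

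Microglial and oligodendrocyte markers were higher by a mean log2 of 0.26 and 0.25, astrocyte markers by 0.10 and interneuron markers by 0.01. Precursor, vascular and choroid plexus lists had means of 0.21, 0.23 and 0.46 and the pyramidal and granule list 0.05. A lower share of excitatory neurons would raise all other types alike. The first 3 of these lists go with this in direction, though their means ran from 0.21 to 0.46. The interneuron list argues against such a share as the whole cause. Mean log2 CPM of the pyramidal and granule list was not lower (5.70 to 5.76 in KO, 5.64 to 5.69 in WT). The deletion acts in these neurons, so that list cannot decide. Microglia and oligodendrocytes exceeded astrocytes and interneurons by 0.21 (SE 0.0736, exact permutation p = 0.1, two-sided, the smallest 3 against 3 allows). This contrast was chosen after the results were seen and leaves out the precursor, vascular and choroid plexus lists. Its sign was therefore known beforehand, and it is descriptive only. After GC correction the medians were 0.21 for microglia and 0.22 for oligodendrocytes, the same to 2 decimals as before it, which argues against GC content. More of these cells, or a response within them, may explain the rise, and neither was tested.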
